A study of Mus musculus with 18 samples.

How the data were processed

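The study measured gene expression on 18 mouse expression arrays, 1 per sorted cell sample, and the deposited table held 41345 probe sets per array with 0 missing values. Its values are deposited log2 intensities (lowest 1.19, highest 13.4), made with RMA and analysed with Partek per the submitters' processing notes, which give no versions and no order of steps. The labels name no array build. Of the probe sets 23521 carried 1 gene symbol, 1814 several and 16010 none in the deposited probe table, and those with several or none were left out. Of the gene identifiers 23328 were found in the RefSeq table and 0 symbols were updated. A gene with more than 1 probe set (1082 of 22180 genes) took the probe set with the highest mean over all arrays. Genome positions were not used. No pair of arrays was identical (0 pairs).

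A gene was tested if at least 3 arrays exceeded the 40th percentile of their own values, which kept 16011 genes and left out 6169 as dim. All comparisons used limma 3.58.1 in R 4.3.3 with 1 mean per sorted population over all 18 arrays (13 residual and 3.8 prior degrees of freedom), limma's moderated test, two-sided, and Benjamini-Hochberg adjustment within each comparison. The threshold was an adjusted p of 0.05. The p-values measure the spread in the deposited values, which lack variation between tumors common to the populations (below). The 13 degrees of freedom count it, so p-values tend to be too small. Figures were drawn with matplotlib 3.10.9, pandas 2.3.3 and Python 3.11.15. The comparisons, gene lists, rule for named genes and most alternative settings were chosen before the data were examined.

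The array medians of muscle (5.041 to 5.105) lay apart from those of tumor (5.410 to 5.438), so each array was centred on its median for the gene changes and counts of tumor against muscle. The fit was tested on simulated data, 10 simulations with 200 of 16011 genes changed. For the muscle comparison it recovered 54.3%, 92.5% and 99.4% of changes of 1.5-fold, 2-fold and 4-fold, and 16% of its calls were false. For the marked against unmarked Pecam1-negative tumor cells it recovered 67.9%, 95.4% and 99.7%, and 13.6% of its calls were false. The false share thus exceeded the nominal 5%. With the repeat number as a block, 33.3%, 87% and 99.2% were recovered in muscle with 6% false, and 51.2%, 92.1% and 99.5% in tumor with 4.3% false. Counts from the block therefore stand beside those without it.

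Whether repeat numbers pair the samples was checked on deviations from the population means, as correlations across genes, which are not independent replicates. In muscle the 3 same-numbered pairs correlated at r = 0.27 to 0.31 (mean 0.29) and the others at -0.19 to -0.09, so the numbers pair these samples. In tumor the mean over the populations of each repeat number was equal for every number, within 7.67e-05 at all 41345 probe sets, which makes same-numbered arrays deviate oppositely (r = -0.72 to -0.17, mean -0.49), so there the check is void. In muscle the median range of these means was 0.248. Within tumors a block of repeat numbers is unaffected by a removed mean, but against muscle it joins different animals. Pairs of a muscle and a tumor array with the same number correlated at -0.11 to 0.07.

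The named genes were, in every comparison, Pecam1, Fabp4, Smo, Gli1, Ptch1, Hhip, Pax7, Myod1 and Myog. To these came the 8 largest and 8 smallest log2 fold changes among genes past the threshold whose groups did not overlap, without symbols of the forms Gm with digits, Rik, LOC, Mir and Snor, while accession-like ones such as AF357355 stayed in. From each list described, up to 4 members with the smallest adjusted p and any member of a list of which 5 or fewer passed were named. Members on the smaller side of a described list were named after their values were seen. Groups of 3 against 3 fail to overlap by chance in 10% of genes. Named genes of tumor against muscle are given on centred values and their sensitivity on deposited values.

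The 25 gene lists were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, with adjustment over 175 tests. Of these 105 were called, 15 of them also with an estimated correlation, and 99 also by fry in the same direction. Fry tests whether a list's genes move on balance one way and does not compare the list with other genes. Counts adjusted over the list alone are given where they differ from those over all genes. Other lists, on mast cells, antigen presentation, activated and venular endothelium, muscle capillary fatty acid handling, tip cells and salivary glands, were written after the data were seen and tested in 42 tests on centred values.

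The alternatives were no filter or a 60th percentile filter, quantile normalization, centring, the mean of all probe sets of a gene, a trended and robust variance, array weights, only the groups compared, an adjusted p of 0.01, at least a 2-fold change, the repeat number as a fixed or random block, tumors aged 48 days only, and each array left out. Leaving out muscle repeats 1 and 2 and combining the block with 48-day tumors were added after the data were seen.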

Results

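Gene expression was measured on 18 arrays, each hybridised with RNA from cells sorted by flow cytometry out of digested tissue. All mice carried aP2-Cre, a Cre recombinase driven by the promoter of the fatty acid binding protein gene Fabp4, and a Cre-dependent tdTomato reporter, so that cells with past or present Cre activity were Tomato-positive. Normal sternocleidomastoid muscle, a neck muscle, at postnatal day 21 gave Tomato-positive and Tomato-negative cells (n = 3 arrays each). Tumors of mice that also carried SmoM2, an active form of the hedgehog signal transducer Smoothened, gave Tomato-negative/Pecam1-negative, Tomato-positive/Pecam1-negative and Tomato-positive/Pecam1-positive cells (n = 4 arrays each). Repeats 1 to 3 of the tumors were taken at day 48 and repeat 4 at day 38. Pecam1 is an adhesion molecule of endothelial cells and leukocytes. Within a group the arrays correlated at r = 0.973 to 0.99 across genes, and the principal components 1 and 2 held 52.8% and 22.5% of the variance. Values are deposited log2 intensities, changes are log2 unless given as fold, means are given with SD, and the number of arrays limits the precision.

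The muscle comparison asked which cells of normal muscle carried the aP2-Cre mark. Endothelial genes were higher in Tomato-positive cells, and genes of fibroblasts, tendon cells, Schwann cells and muscle precursors were higher in Tomato-negative cells. The tenocyte call was lost with an estimated correlation (adjusted p = 0.0879). Kdr and Flt1 encode receptors for vascular endothelial growth factor: Kdr rose 20.8-fold (11.03 ± 0.14 against 6.65 ± 0.39, adjusted p = 1.05e-09) and Flt1 19.8-fold (11.08 ± 0.04 against 6.77 ± 0.38, adjusted p = 4.58e-09; SD, n = 3 each throughout). Lum and Dcn encode proteoglycans of the collagen matrix: Lum fell by 6.48 (4.04 ± 0.15 against 10.52 ± 0.15, adjusted p = 1.58e-11) and Dcn fell by 5.36. Pax7 marks muscle stem cells, Myod1 commits cells to muscle and Myog drives myoblast differentiation: Pax7 fell by 2.93 (5.41 ± 0.57 against 8.34 ± 0.46, adjusted p = 7.61e-06), Myod1 fell by 2.46 (adjusted p = 7.32e-07) and Myog fell by 4.0 (5.74 ± 0.32 against 9.74 ± 0.60, adjusted p = 3.98e-08). Fabp4 itself rose 3-fold (12.45 ± 0.06 against 10.86 ± 0.23, adjusted p = 0.000517) and Pecam1 8.47-fold (adjusted p = 1.36e-09).

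Hedgehog genes were not higher in the marked muscle cells. Gli1, a transcription factor and target of the pathway, fell by 1.02 (5.01 ± 0.16 against 6.02 ± 0.14, adjusted p = 0.00911), and Smo fell by 1.04 (adjusted p = 2.75e-05). The receptor and target gene Ptch1 differed by -0.05 (adjusted p = 0.923) and did not pass the threshold, nor did the pathway inhibitor Hhip (adjusted p = 0.233, and 0.0048 in a fit of only these groups). Its level in the marked cells (3.54 ± 0.24 against 4.61 ± 0.41) lay under the lower quartile of the arrays, so no size is given. Besides Kdr and Flt1, the 8 largest increases were those of Car4, Aplnr, Myct1, Dach1, Ablim3 and Clic5 (4.30 to 4.53). Besides Lum and Dcn, the 8 largest decreases were those of AF357355, Dpt, Kera, Ogn, AF357425 and Mrln (-6.01 to -5.13). In these 16 genes the values of both groups did not overlap.

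All 35 measured endothelial genes rose (median 3.44, adjusted p = 1.31e-32, and 0.0234 with an estimated correlation), among them Nos3, the endothelial nitric oxide synthase (3.05, adjusted p = 6.93e-12), Arhgef15 (3.66), the guidance receptor Robo4 (3.83) and She (3.56). The lymphatic endothelial list went the other way (1 up, 6 down of 7, median -1.65, adjusted p = 0.0025, and 0.0996 with an estimated correlation): Prox1, which specifies lymphatic identity, fell by 3.50, Pdpn by 3.39 and Reln by 2.21, while Flt4, also found on blood capillaries, rose by 2.15. Of 23 fibro-adipogenic and fibroblast genes 21 fell and 2, Fbln2 and Tcf4, rose (median -3.19, adjusted p = 1.54e-16, and 0.0452 with an estimated correlation), Serpinf1 by 3.15, Mmp2 by 4.94, Mfap5 by 4.90 and Gsn by 4.30. Myogenic progenitor genes fell in 16 of 19 cases (median -2.40, adjusted p = 2.5e-09, and 0.0452 with an estimated correlation), with Megf10 at -4.21, Sdc4 at -2.73, Dag1 at -1.99 and Msc at -2.40. All 9 Schwann and glial genes fell (median -1.99, adjusted p = 1.09e-06, and 0.0452 with an estimated correlation), among them the myelin genes Mbp (-2.15) and Pmp22 (-2.28), Cdh19 (-2.98) and Erbb3 (-1.99). The adipocyte list was split (4 up, 4 down of 16, median -0.02, mean 0.19, test upward, adjusted p = 0.589): the lipid genes Pparg (3.36), Cd36 (2.47) and Fabp5 (2.13) rose with Fabp4, and the glucose transporter gene Slc2a4 fell by 1.61.

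The preset correlation in muscle also called the lists hedgehog targets (0 up, 7 down of 17, median -0.35) and hedgehog components (0 up, 6 down of 11, median -0.39). Myoblast differentiation (2 up, 14 down of 18, 3 and 14 over the list alone, median -1.07) and sarcomere (0 up, 23 down of 34, 0 and 26 over the list alone, median -1.83) were called. Tenocyte (0 up, 8 down of 8, median -4.13) and pericyte and smooth muscle (0 up, 8 down of 13, 0 and 9 over the list alone, median -1.97) were called. Macrophage and monocyte (0 up, 11 down of 20, median -0.86) and lymphocyte (0 up, 6 down of 11, 0 and 8 over the list alone, median -1.27) were called. Neutrophil (0 up, 4 down of 9, 0 and 5 over the list alone, median -0.78, with S100a8, S100a9, Retnlg and Cxcr2) and pan-leukocyte (0 up, 6 down of 10, median -1.35) were called. Cell cycle (0 up, 23 down of 29, median -1.25) and mesenchymal transition factors (1 up, 7 down of 13, 2 and 7 over the list alone, median -0.90) were called. Rhabdomyosarcoma reference (0 up, 12 down of 20, median -1.05) and imprinted growth network (0 up, 10 down of 11, median -0.93) were called. Ribosomal proteins (0 up, 12 down of 18, 0 and 6 with the block, median -0.29) was called. These 15 lists in muscle had adjusted p = 2.16e-08 to 0.039, and their calls were lost with an estimated correlation (adjusted p = 0.0879 to 0.505). Not called in muscle were the lists Notch pathway (6 up, 5 down of 14, 7 and 5 over the list alone, median 0.44) and head mesoderm (1 up, 3 down of 8, median -0.14, with Msc, Six2, Tbx3 and Tcf21). Erythroid (0 up, 1 down of 2, median -0.40, with Slc4a1) and dissociation stress (1 up, 1 down of 17, 0 and 0 over the list alone, 2 and 4 with the block, median -0.08, with Nr4a1 and Hspa1a) were not called. The uncalled lists in muscle had adjusted p = 0.163 to 0.889. Cxcr2 lost its call without marked muscle repeats 1, 2 or 3 or unmarked muscle repeats 1, 2 or 3 (adjusted p = 0.0593 to 0.135), and Hspa1a without marked muscle repeats 1 or 3 or unmarked muscle repeat 2 (adjusted p = 0.0983 to 0.285). Nr4a1 lost its call without unmarked muscle repeats 1 or 3 or marked muscle repeat 2 (adjusted p = 0.132 to 0.289), and Retnlg without unmarked muscle repeat 3 (adjusted p = 0.0682). Tcf21 lost its call without marked muscle repeat 1 or unmarked muscle repeat 3 (adjusted p = 0.0628 to 0.0775). Cxcr2 lost the call with the repeat number as a block (adjusted p = 0.118). Cxcr2, Fbln2, Hspa1a, Nr4a1, Retnlg and Tcf21 lost the call without muscle repeats 1 and 2 (adjusted p = 0.0885 to 0.607).

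In muscle 6352 of the 16011 genes tested passed an adjusted p of 0.05, 3065 higher and 3287 lower in Tomato-positive cells, and 5192 passed with the repeat number as a block (2498 and 2694). Of 20 salivary gland genes 6 were over 1 (log2) higher in the mean of muscle repeats 1 and 2 than in repeat 3 in both populations. Without repeats 1 and 2, with 1 array left per muscle population, Fabp4 stood at 1.27, Gli1 at -1.06, Smo at -0.69 and Slc2a4 at -1.05. The calls of Fabp4, Gli1 and Smo were then lost, which fewer arrays alone can bring about.

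**Figure D1:**
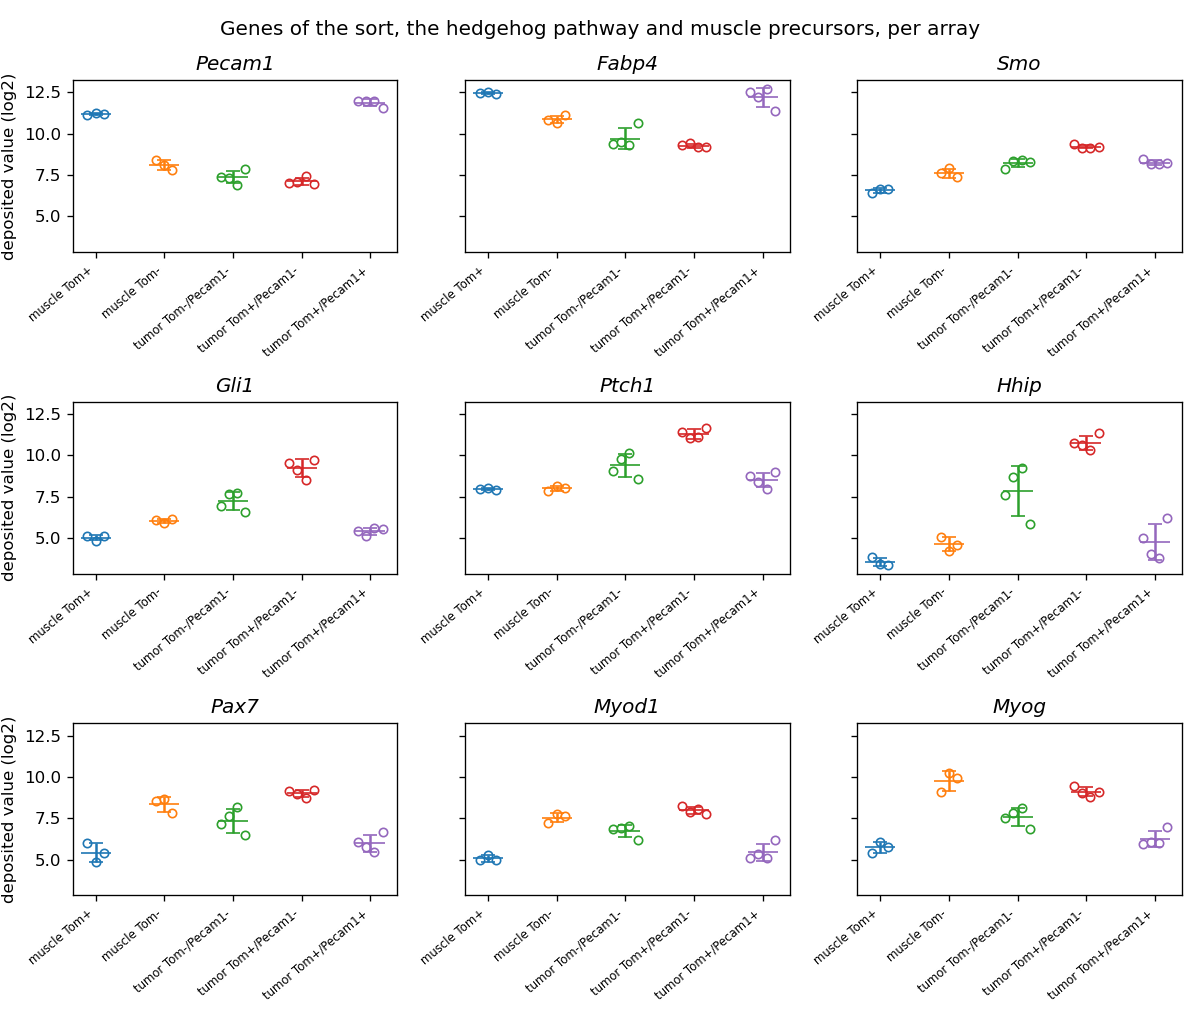
Deposited value (log2, vertical axis) of 9 genes fixed beforehand in the 5 sorted populations (horizontal axis), with 1 circle per array and the mean with SD as a bar. Gli1, Ptch1 and Hhip were highest in tumor Tomato-positive/Pecam1-negative cells (9.22, 11.30 and 10.74), and Pecam1, on which the tumor cells were sorted, in tumor Tomato-positive/Pecam1-positive cells (11.88).

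Among the Pecam1-negative tumor cells, marked cells were compared with unmarked ones to ask what the marked tumor cells expressed. Hedgehog targets and muscle genes were higher in the Tomato-positive cells, and genes of leukocytes and tendon cells were lower. The calls of the muscle, leukocyte and tenocyte lists were lost with an estimated correlation (adjusted p = 0.0796 to 0.253). Gli1 rose 3.99-fold (9.22 ± 0.53 against 7.22 ± 0.56, adjusted p = 3.06e-05), Ptch1 rose 3.77-fold (11.30 ± 0.28 against 9.38 ± 0.70, adjusted p = 8.71e-05) and Hhip rose 7.41-fold (10.74 ± 0.43 against 7.85 ± 1.51, adjusted p = 0.00155); SD, n = 4 each throughout. Smo rose 1.99-fold (9.21 ± 0.10 against 8.22 ± 0.25, adjusted p = 5.12e-05); the labels do not say whether its probes also read the SmoM2 transcript. Of the muscle regulators, Pax7 rose 3.16-fold (9.02 ± 0.22 against 7.35 ± 0.73, adjusted p = 0.00144), Myod1 2.34-fold (adjusted p = 0.000857) and Myog 2.86-fold (adjusted p = 0.0011). S100a8, an inflammatory calcium-binding protein of neutrophils, fell by 5.86 (4.96 ± 0.33 against 10.82 ± 0.36, adjusted p = 9.64e-10). Neither Fabp4 (-0.43, adjusted p = 0.271) nor Pecam1 (-0.26, adjusted p = 0.294) passed the threshold.

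Besides Hhip, the 8 largest increases were those of Adamdec1, Tcf21, a transcription factor of head and heart mesoderm, Col6a5, Sostdc1, Tmem171, Sln, which regulates the muscle calcium pump, and the long noncoding RNA Fendrr (2.18 to 3.75). The 8 largest decreases besides S100a8 were those of the mast cell proteases Mcpt4 (-5.19) and Cpa3 (-4.26), Retnlg, Il1r2, Stfa2l1, S100a9 and Ifi205 (from -5.19 to -4.04). In these 16 genes the values of both groups did not overlap.

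Of 17 measured hedgehog targets 11 rose and 3, Osr1, Sfrp1 and Ccnd2, fell (13 and 4 over the list alone, median 1.01, adjusted p = 0.000329, and 0.0452 with an estimated correlation), with Foxf2 (2.03, adjusted p = 2.04e-07) and Bmp4 (1.33, adjusted p = 1.98e-05) among the highest. Sarcomere genes rose in 24 of 34 cases and fell in 0 (27 and 0 over the list alone, median 1.35, adjusted p = 6.28e-13, and 0.112 with an estimated correlation), among them the giant spring protein Ttn (1.83), Myh1 (1.53), Mybpc1 (1.34) and Tnni1 (1.33). Myoblast differentiation genes rose in 15 of 18 cases and fell in 1, Mef2a (16 and 2 over the list alone, median 1.21, adjusted p = 8.83e-08, and 0.112 with an estimated correlation), among them Myf6 (1.55), the receptor genes of the nerve-muscle synapse Chrnb1 (1.19) and Musk (1.45), and Klhl41 (1.57). In the list of genes known from rhabdomyosarcoma, a tumor with muscle features, 15 of 20 rose (16 over the list alone, adjusted p = 7.49e-07, and 0.13 with an estimated correlation), including the embryonic myosin Myh3 (1.87), the receptor Fgfr4 (1.43) and Cdkn2a (0.66). The leukocyte lists went the other way: all 9 neutrophil genes fell (median -3.41, adjusted p = 1.21e-10, and 0.0796 with an estimated correlation). All 10 pan-leukocyte genes fell (median -2.03, adjusted p = 5.52e-11, and 0.112 with an estimated correlation), as did 19 of 20 macrophage and monocyte genes (median -1.33, adjusted p = 2.08e-13, and 0.112 with an estimated correlation). Examples were the chemokine receptor Cxcr2 (-2.62) among neutrophil genes, Arhgdib (-1.60), Lcp1 (-1.89), Cd53 (-2.27) and Coro1a (-2.14) among pan-leukocyte genes, and Fcer1g (-1.67), Tyrobp (-1.79), Cd14 (-2.07) and Itgam (-2.20) among macrophage genes. Tenocyte genes fell in 6 of 8 cases (median -1.82, 7 over the list alone, adjusted p = 6.58e-07, and 0.0796 with an estimated correlation), with Tnmd at -2.84, Chad at -3.17, Thbs4 at -1.74 and Kera at -3.05.

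The preset correlation in this comparison also called the lists myogenic progenitor (11 up, 2 down of 19, median 0.58) and adipocyte (1 up, 6 down of 16, 1 and 8 over the list alone, median -0.39). Lymphocyte (0 up, 10 down of 11, median -1.78) and Schwann and glial (1 up, 5 down of 9, median -0.37) were called. Imprinted growth network (7 up, 0 down of 11, 8 and 0 over the list alone, 2 and 0 with the block, median 0.59) and dissociation stress (0 up, 2 down of 17, 0 and 1 over the list alone, 0 and 6 with the block, median -0.35, with Btg2 and Atf3) were called. These 6 lists in this comparison had adjusted p = 2.84e-08 to 0.0336, and their calls were lost with an estimated correlation (adjusted p = 0.116 to 0.671). Not called in this comparison were the lists endothelial (5 up, 6 down of 35, 7 and 6 over the list alone, 5 and 3 with the block, median -0.05, mean 0.01) and lymphatic endothelial (2 up, 1 down of 7, 3 and 2 over the list alone, median -0.11, mean 0.09, test upward, with Prox1, Lyve1 and Pdpn). Notch pathway (6 up, 1 down of 14, median 0.24) and hedgehog components (4 up, 0 down of 11, 5 and 0 over the list alone, median 0.27, with Smo, Gli2, Cdon and Sufu) were not called. Head mesoderm (4 up, 0 down of 8, 4 and 1 over the list alone, median 0.27, with Tcf21, Tbx3, Tbx1 and Isl1) and fibro-adipogenic and fibroblast (1 up, 7 down of 23, median -0.03) were not called. Pericyte and smooth muscle (2 up, 2 down of 13, 3 and 3 over the list alone, median -0.02, with Anpep, Higd1b, Des and Notch3) and erythroid (0 up, 1 down of 2, 0 and 2 over the list alone, median -0.44, with Klf1) were not called. Cell cycle (0 up, 2 down of 29, 0 and 1 over the list alone, median 0.12, with Pcna and Mcm3) and mesenchymal transition factors (4 up, 1 down of 13, 5 and 1 over the list alone, median 0.07, with Tgfb2, Cdh2, Zeb1, Snai1 and Twist1) were not called. Ribosomal proteins (0 up, 0 down of 18, median 0.0) was not called. The uncalled lists in this comparison had adjusted p = 0.0554 to 0.927. Atf3 lost its call without unmarked tumor repeats 1, 2 or 3 or marked tumor repeats 1, 2 or 3 (adjusted p = 0.0509 to 0.0917), and Btg2 without unmarked tumor repeat 1 (adjusted p = 0.0617). Klf1 lost its call without unmarked tumor repeats 1, 2 or 4 or marked tumor repeats 1, 2, 3 or 4 (adjusted p = 0.0571 to 0.119), and Mcm3 without unmarked tumor repeats 1 or 4 or marked tumor repeats 1 or 4 (adjusted p = 0.0548 to 0.0745). Mef2a lost its call without unmarked tumor repeats 1, 3 or 4 or marked tumor repeats 1, 2 or 3 (adjusted p = 0.0582 to 0.0898), and Notch3 without unmarked tumor repeats 1 or 4 or marked tumor repeats 1 or 2 (adjusted p = 0.0536 to 0.0758). Pdpn lost its call without unmarked tumor repeats 1, 2 or 3 or marked tumor repeats 1, 2 or 3 (adjusted p = 0.0515 to 0.0924), and Sfrp1 without unmarked tumor repeat 1 or marked tumor repeat 4 (adjusted p = 0.0503 to 0.0511). Twist1 lost its call without unmarked tumor repeat 4 or marked tumor repeat 4 (adjusted p = 0.053 to 0.0668). Klf1, Mef2a, Notch3, Pdpn and Sfrp1 lost the call with the repeat number as a block (adjusted p = 0.0507 to 0.124). The Notch pathway list was called with the block (adjusted p = 0.0362), and with an estimated correlation it had adjusted p = 0.274.

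Between these tumor populations 4065 genes passed (2141 higher and 1924 lower in Tomato-positive cells), and 2693 with the repeat number as a block (1288 and 1405). Of those that changed at least 2-fold 304 were higher and 692 lower.

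Pecam1-positive and Pecam1-negative marked tumor cells were compared. The sort was on Pecam1, so Pecam1 (27.4-fold, adjusted p = 5.52e-13) and the endothelial list are no findings. Endothelial genes were higher in the Pecam1-positive cells, and hedgehog targets, muscle genes and connective tissue genes were lower. The myoblast differentiation, sarcomere, fibroblast and tenocyte calls were lost with an estimated correlation (adjusted p = 0.0736 to 0.145). Podxl, a sialomucin of the vessel surface, rose 37.5-fold (10.67 ± 0.23 against 5.44 ± 0.21, adjusted p = 4.4e-14; SD, n = 4 each throughout). Hedgehog genes fell: Gli1 fell by 3.82 (5.40 ± 0.21 against 9.22 ± 0.53, adjusted p = 1.06e-09), Ptch1 by 2.78 (adjusted p = 1.56e-07), Hhip fell by 6.0 (4.74 ± 1.09 against 10.74 ± 0.43, adjusted p = 1.68e-07) and Smo by 0.97 (adjusted p = 9.65e-06). Pax7 fell by 3.04 (5.98 ± 0.52 against 9.02 ± 0.22, adjusted p = 7.37e-07), Myod1 fell by 2.53 (adjusted p = 6.71e-08) and Myog by 2.85 (adjusted p = 3.34e-07). Fabp4 rose 7.59-fold (12.19 ± 0.58 against 9.27 ± 0.13, adjusted p = 8.76e-08).

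The 8 largest increases besides Podxl were those of Mall, Myct1, Adgrl4, Flt1, the capillary lipase anchor Gpihbp1, Clic5 and Kdr (5.23 to 5.74). Besides Hhip, the 8 largest decreases were those of AF357355, AF357425, Lum, Dpt, Abca8a and the collagen genes Col12a1 and Col6a1 (-5.0 to -4.83). All 35 endothelial genes rose (median 4.20, adjusted p = 5.27e-36, and 0.0223 with an estimated correlation), Tie1 by 4.88, Esam by 4.36, Robo4 by 4.66 and Nos3 by 3.53. Of 17 hedgehog targets 14 fell and 1, Ccnd2, rose (median -1.41, adjusted p = 1.16e-05, and 0.0234 with an estimated correlation), with Rab34 at -4.15, Foxf2 at -2.60 and Igf2 at -2.85. Myogenic progenitor genes fell in 15 of 19 cases (median -2.11, adjusted p = 1.25e-08, and 0.0452 with an estimated correlation), among them Megf10 (-3.93), Heyl (-3.77), Sdc4 (-2.98) and Cdh15 (-2.81). Of 8 head mesoderm genes 6 fell (median -1.01, adjusted p = 0.00177, and 0.0452 with an estimated correlation), Tcf21 by 4.48, Tbx1 by 1.79, Isl1 by 1.04 and Msc by 0.99. The sarcomere list fell as well (0 up, 32 down of 34, median -2.50, adjusted p = 5.88e-15, and 0.103 with an estimated correlation), with Neb at -4.16, Ttn at -4.06, Myom1 at -3.08 and Tpm2 at -3.02.

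The preset correlation between the marked tumor populations also called the lists hedgehog components (3 up, 7 down of 11, median -0.97) and myoblast differentiation (2 up, 16 down of 18, median -1.63). Fibro-adipogenic and fibroblast (2 up, 19 down of 23, median -3.25) and tenocyte (0 up, 7 down of 8, median -2.25) were called. Pericyte and smooth muscle (1 up, 10 down of 13, median -1.29) and macrophage and monocyte (0 up, 19 down of 20, median -2.23) were called. Pan-leukocyte (1 up, 5 down of 10, 0 and 3 with the block, median -0.92) and cell cycle (1 up, 13 down of 29, median -0.40) were called. Mesenchymal transition factors (0 up, 9 down of 13, median -1.14) and rhabdomyosarcoma reference (1 up, 15 down of 20, median -1.98) were called. Imprinted growth network (0 up, 10 down of 11, 1 and 10 over the list alone, median -1.42) was called. These 11 lists between the marked tumor populations had adjusted p = 2.95e-13 to 0.0349, and their calls were lost with an estimated correlation (adjusted p = 0.0736 to 0.694). Not called between the marked tumor populations were the lists lymphatic endothelial (2 up, 3 down of 7, median -0.36, with Pdpn, Flt4, Prox1, Mmrn1 and Foxc2) and Notch pathway (6 up, 6 down of 14, median 0.03). Adipocyte (5 up, 4 down of 16, median 0.07) and lymphocyte (0 up, 0 down of 11, median 0.12) were not called. Neutrophil (0 up, 0 down of 9, median 0.12) and erythroid (1 up, 0 down of 2, median 0.23, with Klf1) were not called. Schwann and glial (0 up, 3 down of 9, median 0.01, mean -0.75, test downward, with S100b, Erbb3 and Pmp22) and dissociation stress (0 up, 2 down of 17, 0 and 0 over the list alone, 2 and 2 with the block, median -0.04, with Hspa1a and Hspa1b) were not called. Ribosomal proteins (0 up, 3 down of 18, 0 and 1 over the list alone, 0 and 1 with the block, median -0.11, with Rpl5, Rpl10a and Rps4x) was not called. The uncalled lists between the marked tumor populations had adjusted p = 0.173 to 0.952. Foxc2 lost its call without Pecam1-negative tumor repeats 1 or 4 or Pecam1-positive tumor repeats 1 or 4 (adjusted p = 0.0696 to 0.12), and Hspa1a without Pecam1-negative tumor repeat 4 (adjusted p = 0.0596). Hspa1b lost its call without Pecam1-positive tumor repeat 3 or Pecam1-negative tumor repeat 4 (adjusted p = 0.05 to 0.0778), and Klf1 without Pecam1-positive tumor repeat 3 (adjusted p = 0.0609). Rpl10a lost its call without Pecam1-positive tumor repeats 1 or 3 or Pecam1-negative tumor repeats 3 or 4 (adjusted p = 0.0587 to 0.0768), and Rps4x without Pecam1-negative tumor repeats 2, 3 or 4 or Pecam1-positive tumor repeat 3 (adjusted p = 0.0504 to 0.0954). Foxc2, Klf1, Rpl10a and Rps4x lost the call with the repeat number as a block (adjusted p = 0.0572 to 0.105).

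Here 7136 genes passed (3360 higher and 3776 lower in Pecam1-positive cells), and 5805 with the block (2669 and 3136).

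Marked Pecam1-positive tumor cells were also compared with unmarked Pecam1-negative ones, which differ in both markers. Endothelial genes, tied to the sort, were higher in the former, and fibroblast, tendon cell and leukocyte genes were lower. The tenocyte and leukocyte calls were lost with an estimated correlation (adjusted p = 0.0677 to 0.317). Emcn encodes a sialomucin of endothelium: Emcn rose 46.4-fold (11.94 ± 0.35 against 6.40 ± 0.70, adjusted p = 4.14e-11), while Lum fell by 5.33 (5.36 ± 0.41 against 10.70 ± 0.32, adjusted p = 8.59e-12); SD, n = 4 each throughout. The 8 largest increases were those of Adgrl4, Emcn, Myct1, Gpihbp1, Podxl, Kdr, Cyyr1 and Mall (5.27 to 5.61) and the 8 largest decreases those of Lilrb4a, Chad, S100a8, Dpt, Il1b, Thbs4, Cilp and Lum (-6.29 to -5.33). Probe sets of Cyyr1 differed (0.51 to 5.30, with 2.90 as their mean). Gli1 fell by 1.82 (adjusted p = 1.23e-05) and Hhip by 3.11 (adjusted p = 0.000321). Ptch1 fell by 0.87 (adjusted p = 0.0152), a call lost with the repeat number as a block (adjusted p = 0.0549) and in a fit of only these groups (adjusted p = 0.0725). It was also lost without the unmarked array of repeat 2 (adjusted p = 0.0546), that of repeat 3 (adjusted p = 0.0626) or the Pecam1-positive array of repeat 3 (adjusted p = 0.0598). Smo differed by 0.02 (adjusted p = 0.924). Pax7 fell by 1.38 (adjusted p = 0.00279), Myod1 by 1.31 (adjusted p = 0.000163) and Myog by 1.33 (adjusted p = 0.00132). Fabp4 rose 5.63-fold (adjusted p = 7.43e-07), and Pecam1, sorted on, 22.9-fold (adjusted p = 1.51e-12).

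All 35 endothelial genes rose (median 4.21, adjusted p = 7.83e-37, and 0.0223 with an estimated correlation), with Tie1 at 4.97, Vwf at 4.39, Esam at 4.21 and Nos3 at 3.46. Of 23 fibro-adipogenic and fibroblast genes 21 fell and 2, Fbln2 and Tcf4, rose (median -3.42, adjusted p = 1.97e-16, and 0.0452 with an estimated correlation), with Col6a1 at -4.33, Mfap5 at -4.14, Mmp2 at -3.98 and Serpinf1 at -2.15. All 20 macrophage and monocyte genes fell (median -3.58, adjusted p = 1.75e-17, and 0.0793 with an estimated correlation), Tyrobp by 5.01, Lyz2 by 4.41, Mpeg1 by 4.36 and Fcer1g by 3.77. The preset correlation across both markers also called the lists hedgehog targets (2 up, 10 down of 17, 4 and 10 over the list alone, median -0.57) and myogenic progenitor (0 up, 14 down of 19, 0 and 15 over the list alone, median -1.33). Myoblast differentiation (2 up, 11 down of 18, median -0.69) and sarcomere (0 up, 26 down of 34, median -1.09) were called. Head mesoderm (0 up, 4 down of 8, median -0.46, with Msc, Six2, Tcf21 and Isl1) and tenocyte (0 up, 8 down of 8, median -4.59) were called. Pericyte and smooth muscle (1 up, 12 down of 13, median -1.22) and lymphocyte (0 up, 10 down of 11, median -1.67) were called. Neutrophil (0 up, 9 down of 9, median -3.23) and pan-leukocyte (0 up, 10 down of 10, median -2.92) were called. Schwann and glial (0 up, 7 down of 9, 0 and 8 over the list alone, median -1.0) and cell cycle (1 up, 3 down of 29, median -0.31, with Tyms, Bub1b, Top2a and Rrm2) were called. Mesenchymal transition factors (1 up, 7 down of 13, median -1.42) and rhabdomyosarcoma reference (2 up, 12 down of 20, median -1.0) were called. Imprinted growth network (0 up, 8 down of 11, 1 and 8 over the list alone, median -0.94) was called. These 15 lists across both markers had adjusted p = 3.03e-08 to 0.0384, and their calls were lost with an estimated correlation (adjusted p = 0.0677 to 0.697). Not called across both markers were the lists lymphatic endothelial (2 up, 4 down of 7, median -0.69) and Notch pathway (9 up, 5 down of 14, median 0.52). Hedgehog components (3 up, 6 down of 11, 4 and 6 over the list alone, 1 and 6 with the block, median -0.37) and adipocyte (4 up, 5 down of 16, median -0.11) were not called. Erythroid (0 up, 0 down of 2, median -0.21) and dissociation stress (0 up, 1 down of 17, 0 and 0 over the list alone, 0 and 6 with the block, median -0.39, with Jund) were not called. Ribosomal proteins (0 up, 1 down of 18, 0 and 0 over the list alone, median -0.10, with Rps4x) was not called. The uncalled lists across both markers had adjusted p = 0.0734 to 0.806. Fbln2 lost its call without unmarked tumor repeat 1 or Pecam1-positive tumor repeat 1 (adjusted p = 0.066 to 0.0718), and Jund without unmarked tumor repeat 2 or Pecam1-positive tumor repeat 2 (adjusted p = 0.0731 to 0.0733). Rps4x lost its call without unmarked tumor repeats 1, 3 or 4 or Pecam1-positive tumor repeat 3 (adjusted p = 0.0532 to 0.0966), and Rrm2 without Pecam1-positive tumor repeat 3 (adjusted p = 0.0695). Fbln2 and Rps4x lost the call with the repeat number as a block (adjusted p = 0.0602 to 0.0973). With the block the dissociation stress list was called (adjusted p = 0.00958), and with an estimated correlation it had adjusted p = 0.758.

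Across both markers 6669 genes passed (3277 higher and 3392 lower in the Pecam1-positive cells), and 5448 with the block (2581 and 2867).

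Marked cells of tumors were compared with marked cells of normal muscle, 2 populations that differ in SmoM2, tissue, age, strain and gate at once. Log2 changes in these comparisons are between arrays centred on their medians, since the medians of the tumor arrays lay 0.343 above those of the muscle arrays. In marked Pecam1-negative tumor cells hedgehog, muscle and connective tissue genes were higher, and endothelial genes lower, all tied to the gate. All these list calls but the endothelial one were lost with an estimated correlation (adjusted p = 0.0967 to 0.34). Hhip was higher (deposited mean 10.74 ± 0.43 against 3.54 ± 0.24, adjusted p = 6.25e-08; SD, n = 4 and 3 throughout), with no fold given as the latter lay under the lower quartile of its arrays. Gli1 was 14.6-fold higher (9.22 ± 0.53 against 5.01 ± 0.16, adjusted p = 2.12e-09), Ptch1 8.02-fold (adjusted p = 1.18e-07) and Smo 4.9-fold (adjusted p = 4.98e-10). Pax7 rose 9.62-fold (adjusted p = 5.23e-07), Myod1 5.86-fold (adjusted p = 1.15e-07) and Myog 8.05-fold (adjusted p = 3.23e-07). Fabp4 fell by 3.52 (adjusted p = 1.98e-08) and Pecam1, which the tumor gate excluded, by 4.42 (adjusted p = 3.2e-12).

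Besides Hhip, the 8 largest increases were those of Car3, Lum, Cdh11, Ogn, Smoc1, Postn and Col6a1 (5.33 to 6.51), several of them matrix genes such as the collagen gene Col6a1 and the osteoglycin gene Ogn. The 8 largest decreases were those of Clic5, Gpihbp1, Timp4, Rbp7, Myct1, Dipk2b, Adgrl4 and Rassf9 (-6.34 to -5.73). All 35 endothelial genes fell on centred values (median -4.34, adjusted p = 7.29e-39, and 0.0223 with an estimated correlation), with Gpihbp1 at -6.14, She at -4.75, Esam at -4.18 and Nos3 at -3.70. Of 17 hedgehog targets 14 rose and 2, Ccnd2 and Mycn, fell (median 1.81, adjusted p = 0.00677, and 0.0967 with an estimated correlation), with Rab34 at 4.58, Foxf2 at 2.93 and Foxd1 at 2.36. Sarcomere genes rose in 29 of 34 cases and fell in 1, Myl2 (median 2.29, adjusted p = 1.74e-06, and 0.258 with an estimated correlation), among them Neb (4.76), Ttn (4.19), Myh1 (3.27) and Tnni1 (2.87). The rhabdomyosarcoma list rose in 16 of 20 cases and fell in 2, Mycn and Nos1 (median 2.45, adjusted p = 0.00019, and 0.253 with an estimated correlation), with Myh8 at 4.99, Fbn2 at 4.51, Egfr at 4.48 and Peg3 at 3.23. Fibroblast genes were higher as well (20 up, 2 down of 23, median 3.49, the latter Fbln2 and Tcf4, adjusted p = 4.21e-07, and 0.138 with an estimated correlation), with Mfap5 at 5.18, Mmp2 at 4.77 and Serpinf1 at 3.32.

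The preset correlation against marked muscle cells also called the lists hedgehog components (7 up, 2 down of 11, median 1.45) and myogenic progenitor (16 up, 1 down of 19, median 2.37). Myoblast differentiation (14 up, 2 down of 18, median 1.63) and tenocyte (6 up, 0 down of 8, median 2.15) were called. Macrophage and monocyte (17 up, 0 down of 20, median 1.86) and cell cycle (20 up, 1 down of 29, median 0.86) were called. Mesenchymal transition factors (9 up, 0 down of 13, median 2.05) and imprinted growth network (8 up, 0 down of 11, median 1.44) were called. Ribosomal proteins (8 up, 1 down of 18, deposited 17 and 0, median 0.20) was called. These 9 lists against marked muscle cells had adjusted p = 0.000161 to 0.039, and their calls were lost with an estimated correlation (adjusted p = 0.0967 to 0.629). Not called against marked muscle cells were the lists lymphatic endothelial (5 up, 1 down of 7, median 1.17) and Notch pathway (5 up, 7 down of 14, deposited 5 and 5, median -0.35). Head mesoderm (6 up, 2 down of 8, median 0.79) and adipocyte (5 up, 5 down of 16, deposited 7 and 4, median 0.02, test downward) were not called. Pericyte and smooth muscle (7 up, 1 down of 13, median 1.17) and lymphocyte (1 up, 0 down of 11, median -0.14, deposited 0.20, with Il7r) were not called. Neutrophil (1 up, 0 down of 9, deposited 3 and 0, median 0.29, test downward, with S100a9) and pan-leukocyte (8 up, 0 down of 10, median 1.07) were not called. Erythroid (0 up, 2 down of 2, median -0.69, with Slc4a1 and Klf1) and Schwann and glial (3 up, 2 down of 9, median -0.20, deposited 0.14, test upward, with Sox10, Mbp, S100b, Erbb3 and Pmp22) were not called. Dissociation stress (2 up, 2 down of 17, deposited 7 and 1, median 0.22, test downward, with Fos, Hspa8, Socs3 and Btg2) was not called. The uncalled lists against marked muscle cells had adjusted p = 0.0955 to 0.897. Btg2 lost its call on deposited values without muscle repeats 1 or 3 or tumor repeats 1 or 2 (adjusted p = 0.0635 to 0.176), and Fbln2 without muscle repeats 1, 2 or 3 or tumor repeats 2, 3 or 4 (adjusted p = 0.0541 to 0.104). Klf1 lost its call without muscle repeats 1 or 3 (adjusted p = 0.0707 to 0.0886), and Mbp without muscle repeat 1 or tumor repeat 4 (adjusted p = 0.0637 to 0.19). Mycn lost its call without muscle repeats 2 or 3 or tumor repeats 3 or 4 (adjusted p = 0.0507 to 0.163). On deposited values without muscle repeats 1 and 2 Fbln2, Il7r, Mbp, Mycn, Myl2, Nos1 and S100a9 lost the call (adjusted p = 0.0518 to 0.332). The list test used deposited values; on centred values the ribosomal proteins list lost its call (adjusted p = 0.242), and the head mesoderm (adjusted p = 0.0463), pericyte and smooth muscle (adjusted p = 0.0346) and pan-leukocyte (adjusted p = 0.0375) lists gained one. With an estimated correlation, on deposited values, these had adjusted p = 0.269, 0.644 and 0.714.

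Of the genes tested 9413 passed on centred values (4730 higher and 4683 lower in tumor) and 10590 on deposited values (8245 and 2345). The means of the tumor repeat numbers were equal in the deposited values, so variation between tumors common to the populations is absent from these p-values and from those of the next comparison. Of 20 salivary gland genes 6 were higher in muscle repeats 1 and 2 (above), and Xist, a transcript of the inactive X chromosome, was 10.17 to 10.85 in the muscle arrays against 5.05 to 5.79 in the tumor arrays.

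The marked Pecam1-positive tumor cells were compared with marked muscle cells to ask how far the endothelial cells of both tissues differed. Smo was 2.48-fold higher in the tumor cells (deposited mean 8.24 ± 0.15 against 6.57 ± 0.15, adjusted p = 4.01e-06; SD, n = 4 and 3 throughout), while no difference past the threshold was found for the targets Gli1 (0.04, adjusted p = 0.929), Ptch1 (0.21, adjusted p = 0.603) and Hhip (4.74 ± 1.09 against 3.54 ± 0.24, adjusted p = 0.323). On deposited values Gli1 passed in a fit of only these groups (0.39, adjusted p = 0.046) and Ptch1 without the tumor array of repeat 3 (0.75, adjusted p = 0.0441). Pax7 (0.22, adjusted p = 0.674), Myod1 (0.0, adjusted p = 0.993), Myog (0.15, adjusted p = 0.74), Fabp4 (-0.61, adjusted p = 0.122) and Pecam1 (0.34, adjusted p = 0.164) did not pass either. Among the largest increases were those of the growth factor Ptn, 18.1-fold (10.12 ± 0.45 against 5.59 ± 0.37, adjusted p = 2.89e-09), the leukocyte adhesion receptor Sele 10.1-fold (10.08 ± 0.52 against 6.39 ± 1.38, adjusted p = 4.11e-05) and Esm1, a proteoglycan of sprouting vessels, 8.88-fold (adjusted p = 1.02e-05). Pparg, a regulator of lipid uptake, fell by 1.87 (7.46 ± 0.38 against 8.97 ± 0.16, adjusted p = 1.98e-06).

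The 8 largest increases further held Ces2g, Olfr726, Olfr1219, Cmah and Slco2a1 (2.62 to 3.67). The 8 largest decreases were those of Xist, Retnla, Smr3a, Klra9, Olfr310, Lamtor3-ps, Amy1 and Timp4 (-5.31 to -2.86). Of these, Smr3a and Amy1 are genes of salivary glands that were higher in muscle repeats 1 and 2 than in repeat 3, and Xist was high in all 6 muscle arrays. The call of Smr3a was lost without the muscle array of repeat 1 (adjusted p = 0.131) or of repeat 2 (adjusted p = 0.0873) and with a random block (adjusted p = 0.0843). The endothelial list was not called (6 up, 7 down of 35, deposited 12 and 1, median -0.15, deposited 0.21, adjusted p = 0.448), with increases of the capillary diaphragm gene Plvap (2.20), the clotting factor carrier Vwf (1.12), Ramp2 (0.78) and Lmo2 (0.82). Hedgehog targets were not called as a list (2 up, 2 down of 17, deposited 7 and 1, median 0.19, test downward, adjusted p = 0.748). Foxf1 (1.90, adjusted p = 5.96e-05) and Foxd1 (0.83) rose. Ccnd2 fell by 1.0 (on deposited values -0.58, adjusted p = 0.0986, without muscle repeats 1 and 2). Mycn fell by 0.60 (adjusted p = 0.0136, and on deposited values -0.25, adjusted p = 0.238), and Foxf2 stood at 0.33 (adjusted p = 0.141).

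The preset correlation between the endothelial populations also called the lists lymphatic endothelial (6 up, 0 down of 7, median 0.75) and pericyte and smooth muscle (1 up, 5 down of 13, median -0.41). Macrophage and monocyte (2 up, 6 down of 20, deposited 3 and 3, median -0.39) and imprinted growth network (0 up, 3 down of 11, deposited 3 and 1, median -0.34, deposited 0.01, with Plagl1, Cdkn1c and Igf2r) were called. Ribosomal proteins (1 up, 0 down of 18, deposited 15 and 0, median 0.04, with Rps23) was called. These 5 lists between the endothelial populations had adjusted p = 0.0031 to 0.0451, and their calls were lost with an estimated correlation (adjusted p = 0.122 to 0.526). Not called between the endothelial populations were the lists Notch pathway (0 up, 5 down of 14, deposited 4 and 0, median -0.37, with Dll4, Jag1, Jag2, Hey1 and Heyl) and hedgehog components (5 up, 0 down of 11, deposited 8 and 0, median 0.25, with Smo, Gli2, Gas1, Ihh and Kif7). Myogenic progenitor (3 up, 4 down of 19, deposited 5 and 1, median 0.0) and myoblast differentiation (0 up, 2 down of 18, deposited 7 and 2, median 0.06, test downward, with Cdkn1c and Tmem182) were not called. Sarcomere (5 up, 4 down of 34, deposited 11 and 3, median -0.03, deposited 0.33) and head mesoderm (1 up, 2 down of 8, deposited 2 and 1, median -0.27, deposited 0.08, with Tbx1, Isl1 and Eya1) were not called. Adipocyte (2 up, 5 down of 16, deposited 7 and 3, median 0.03, test downward) and fibro-adipogenic and fibroblast (8 up, 2 down of 23, deposited 13 and 1, median 0.36) were not called. Tenocyte (1 up, 0 down of 8, median 0.09, test downward, with Thbs4) and lymphocyte (0 up, 0 down of 11, deposited 2 and 0, median -0.06, deposited 0.29) were not called. Neutrophil (1 up, 0 down of 9, deposited 3 and 0, median 0.44, test downward, with S100a8) and pan-leukocyte (1 up, 0 down of 10, median 0.0, with Lcp1) were not called. Erythroid (0 up, 1 down of 2, deposited 0 and 0, median -0.47, with Klf1) and Schwann and glial (1 up, 2 down of 9, deposited 2 and 1, median -0.13, deposited 0.23, with Sox10, Mbp and Pmp22) were not called. Cell cycle (3 up, 0 down of 29, deposited 21 and 0, median 0.30, with Aurkb, Plk1 and Tyms) and mesenchymal transition factors (5 up, 2 down of 13, deposited 9 and 1, median 0.23) were not called. Rhabdomyosarcoma reference (3 up, 2 down of 20, deposited 11 and 0, median 0.16, with Hmga2, Cdh3, Mycn, Met and Nos1) and dissociation stress (1 up, 4 down of 17, deposited 7 and 0, median 0.39, test downward, with Fos, Hspa1a, Hspa1b, Hspa8 and Btg2) were not called. The uncalled lists between the endothelial populations had adjusted p = 0.0625 to 0.859. On deposited but not on centred values Foxf2 (0.68, adjusted p = 0.00238) and Pecam1 (0.70, adjusted p = 0.00471) passed. On centred but not on deposited values, given here, Btg2 (-0.28, adjusted p = 0.225), Heyl (-0.58, adjusted p = 0.118), Hspa1a (-0.53, adjusted p = 0.0872), Hspa1b (-0.65, adjusted p = 0.11) and Jag1 (-0.23, adjusted p = 0.115) passed. Cdkn1c lost its call on deposited values without muscle repeats 1, 2 or 3 or tumor repeats 1, 2 or 3 (adjusted p = 0.0668 to 0.119), and Mbp without muscle repeat 1 (adjusted p = 0.0723). Btg2 gained its call on deposited values without muscle repeat 2 (adjusted p = 0.0325), and Heyl without muscle repeat 2 or tumor repeat 4 (adjusted p = 0.00849 to 0.0301). Hspa1a gained its call without muscle repeat 2 (adjusted p = 0.0182), and Hspa1b without muscle repeat 2 (adjusted p = 0.0165). Jag1 gained its call without tumor repeat 2 (adjusted p = 0.04). On deposited values without muscle repeats 1 and 2 Cdkn1c, Foxf2, Lcp1, Mbp, Pecam1, Plk1 and S100a8 lost the call (adjusted p = 0.0651 to 0.316). On centred values the pericyte and smooth muscle (adjusted p = 0.101), macrophage and monocyte (adjusted p = 0.181), imprinted growth network (adjusted p = 0.228) and ribosomal proteins (adjusted p = 0.565) lists lost their calls. The hedgehog components (adjusted p = 0.0347), fibro-adipogenic and fibroblast (adjusted p = 0.0262) and cell cycle (adjusted p = 0.00759) lists gained one. With an estimated correlation, on deposited values, these had adjusted p = 0.481, 0.786 and 0.758.

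On centred values 5482 genes passed (2513 higher and 2969 lower in tumor), on quantile-normalized values 5593 (2810 and 2783) and on deposited values 8444 (7642 and 802). Without muscle repeats 1 and 2 the count on deposited values was 4945.

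The Tomato contrast in tumor, limited to Pecam1-negative cells, was compared with that in muscle by testing their difference. Muscle and hedgehog genes stood higher with the mark in tumor than in muscle, and endothelial genes lower, all tied to the Pecam1 gate. The hedgehog components, myoblast differentiation and sarcomere calls were lost with an estimated correlation (adjusted p = 0.112 to 0.222). The difference was 4.59 for Pax7 (adjusted p = 1.49e-06), 3.69 for Myod1 (adjusted p = 2.5e-07) and 5.52 for Myog (adjusted p = 4.11e-08). For the hedgehog genes it was 3.01 for Gli1 (adjusted p = 7.03e-06), 1.96 for Ptch1 (adjusted p = 0.001) and 2.03 for Smo (adjusted p = 4.37e-07). It was positive for Hhip (adjusted p = 0.00187), with no size given as the level in marked muscle cells lay under the lower quartile. Fabp4 (-2.02, adjusted p = 0.00082) and Pecam1 (-3.34, adjusted p = 2.74e-08) differed the other way.

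The difference was positive in 15 of 19 myogenic progenitor genes (median 3.14, adjusted p = 4.77e-09, and 0.0452 with an estimated correlation), among them Megf10 (5.57), Fgfr4 (4.82), Dag1 (2.57) and Msc (2.17). Of 17 hedgehog targets it was positive in 12 and negative in 1, Ccnd2 (15 and 1 over the list alone, median 1.55, adjusted p = 7.27e-05, and 0.0348 with an estimated correlation), with Rab34 at 3.64, Bmp4 at 2.48 and Foxf2 at 2.15. It was negative in all 35 endothelial genes (median -3.34, adjusted p = 1.8e-29, and 0.0264 with an estimated correlation), Fli1 at -4.79, Robo4 at -3.90, She at -3.59 and Nos3 at -3.12. With Pecam1-positive tumor cells gated out, no list tests the mark alone. In the sarcomere list (31 up, 0 down of 34, 32 and 0 over the list alone, median 3.19, adjusted p = 1.7e-13, and 0.112 with an estimated correlation) Actc1 stood at 6.14, Mybpc1 at 4.92, Ttn at 4.17 and Myh1 at 3.36. The preset correlation in the difference also called the lists lymphatic endothelial (6 up, 1 down of 7, median 1.34) and hedgehog components (7 up, 0 down of 11, median 0.65). Myoblast differentiation (15 up, 2 down of 18, median 2.01) and head mesoderm (5 up, 0 down of 8, median 0.97, with Msc, Tcf21, Six2, Tbx1 and Isl1) were called. Fibro-adipogenic and fibroblast (19 up, 2 down of 23, 20 and 2 over the list alone, median 3.52) and tenocyte (5 up, 0 down of 8, median 1.71, with Fmod, Thbs4, Tnmd, Scx and Kera) were called. Pericyte and smooth muscle (8 up, 1 down of 13, median 2.03) and neutrophil (0 up, 7 down of 9, 0 and 9 over the list alone, median -2.74) were called. Schwann and glial (6 up, 0 down of 9, 7 and 0 over the list alone, median 0.97) and cell cycle (22 up, 0 down of 29, 23 and 1 over the list alone, median 1.36) were called. Mesenchymal transition factors (7 up, 1 down of 13, 8 and 1 over the list alone, median 0.99) and rhabdomyosarcoma reference (14 up, 0 down of 20, 15 and 0 over the list alone, median 2.18) were called. Imprinted growth network (9 up, 0 down of 11, 11 and 0 over the list alone, median 1.43) and ribosomal proteins (5 up, 0 down of 18, 4 and 0 over the list alone, 3 and 0 with the block, median 0.27, with Rpl10a, Rpl5, Rps3, Rps4x and Rpl8) were called. These 14 lists in the difference had adjusted p = 4.61e-13 to 0.0182, and their calls were lost with an estimated correlation (adjusted p = 0.0736 to 0.439). Not called in the difference were the lists Notch pathway (5 up, 4 down of 14, median 0.15) and adipocyte (3 up, 5 down of 16, 4 and 5 over the list alone, median -0.45). Macrophage and monocyte (1 up, 4 down of 20, 1 and 3 over the list alone, median -0.57, with Itgam, Mpeg1, Cd14, Cd68 and Ccr2) and lymphocyte (0 up, 1 down of 11, median -0.80, with Il7r) were not called. Pan-leukocyte (0 up, 3 down of 10, median -0.77, with Lcp1, Arhgdib and Vav1) and erythroid (0 up, 1 down of 2, median -0.04, with Klf1) were not called. Dissociation stress (0 up, 2 down of 17, median -0.22, with Btg2 and Dusp1) was not called. The uncalled lists in the difference had adjusted p = 0.0773 to 0.752. Ccr2, Kera, Klf1, Rpl8, Rps4x and Vav1 lost the call with the repeat number as a block (adjusted p = 0.0833 to 0.113). Btg2, Ccr2, Cd14, Cd68, Il7r, Itgam, Kera, Mpeg1, Rpl5, Rpl8, Rps4x, Tbx1 and Vav1 lost the call without muscle repeats 1 and 2 (adjusted p = 0.0522 to 0.273).

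The difference passed for 6319 genes (3353 positive and 2966 negative), for 4968 with the block (2676 and 2292) and for 3992 without muscle repeats 1 and 2. Without these repeats the calls of Fabp4 (-1.71, adjusted p = 0.0928), Hhip (adjusted p = 0.0679) and Ptch1 (2.02, adjusted p = 0.052) were lost.

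**Figure D2:**
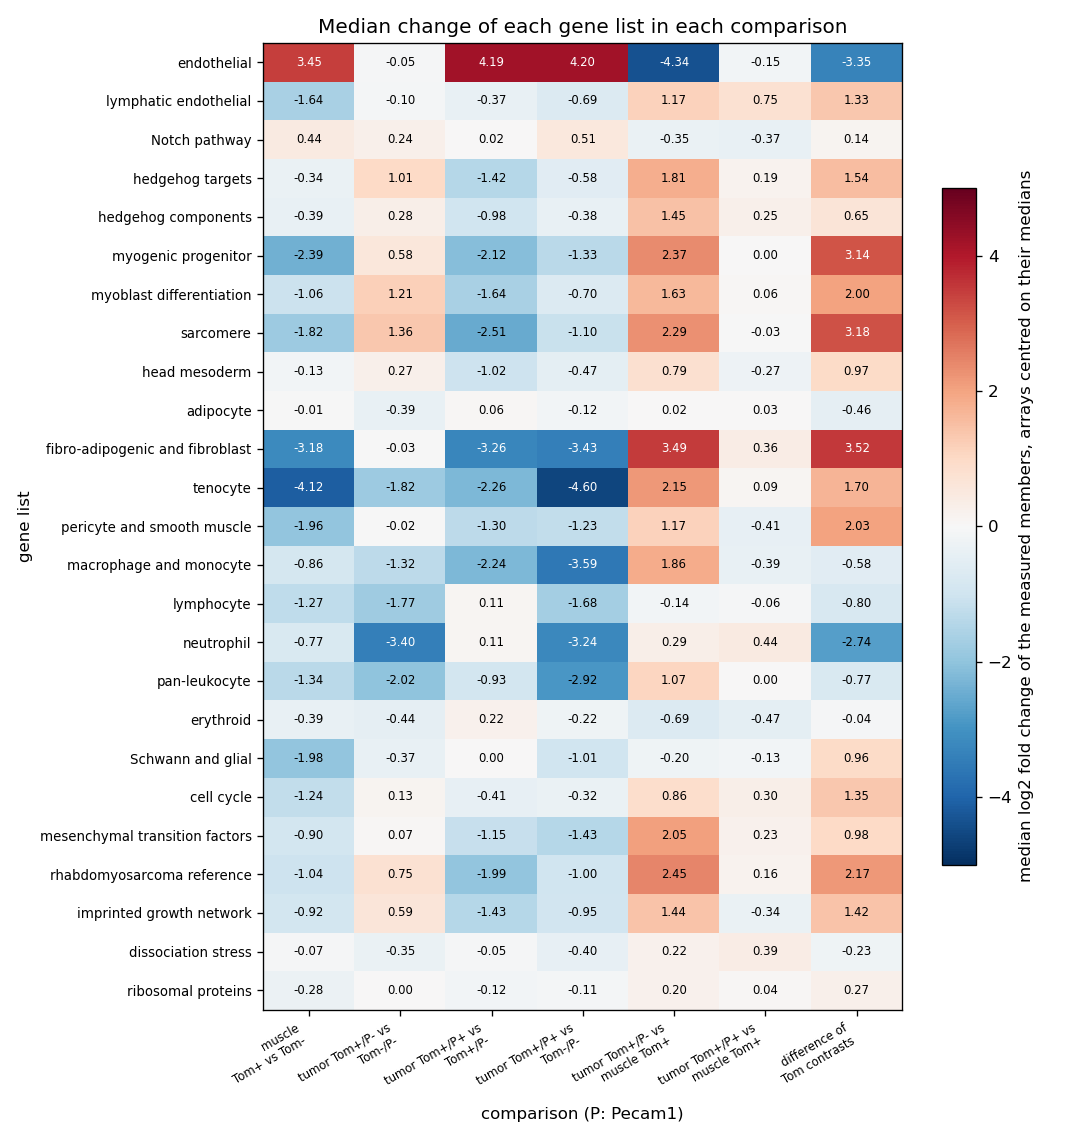
Median log2 fold change of the measured members of each of the 25 gene lists (vertical axis) in each comparison (horizontal axis), with every array centred on its median, red for higher and blue for lower. The endothelial list stood at 3.45 in marked against unmarked muscle cells. In tumor, with Pecam1-positive cells gated out, it was -0.05.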

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

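The tests on salivary gland genes, on Xist and on the removed repeat-number means were chosen after these patterns had been seen. Of 419 named genes and tumor populations tested, 35 had 1 array far from the other 3, by the gap to its nearest neighbour over the range of the 4 arrays, where chance gives about 5 percent. In Tomato-negative/Pecam1-negative cells these were Adamdec1 (0.918), Cdon (0.924), Fabp4 (0.835) and Thbs4 (0.918). In Tomato-positive/Pecam1-negative cells these were Dpt (0.921), Hspa1b (0.863), Lcp1 (0.845), Mfap5 (0.888), Myl2 (0.848), Osr1 (0.958), Pmp22 (0.831), Sufu (0.884) and Thbs4 (0.930). In Tomato-positive/Pecam1-positive cells these were Adgrl4 (0.852), Amy1 (0.833), Cdh15 (0.872), Cdh3 (0.839), Dll4 (0.853), Emcn (0.919), Erbb3 (0.864), Flt1 (0.973), Il1b (0.851), Jund (0.932), Kdr (0.973), Mmrn1 (0.839), Myct1 (0.861), Myog (0.867), Olfr726 (0.910), Pecam1 (0.893), Plagl1 (0.868), Rps23 (0.865), Sele (0.893), Six2 (0.885), Smo (0.8292) and Tie1 (0.830). Repeat 4 was apart in 24 cases, repeat 3 in 6, repeat 1 in 3 and repeat 2 in 2. Equal means tie these arrays, so 5 percent need not hold.

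The Tomato contrast differed between tumor and muscle, by limma's test of the difference itself, for Cxcr2 (-1.71), Fabp4 (-2.02), Gli1 (3.01), Hhip (3.96), Kera (2.17), Myod1 (3.69), Myog (5.52), Pax7 (4.59), Pdpn (3.81), Pecam1 (-3.34), Prox1 (5.04), Ptch1 (1.96), Retnlg (-2.74), S100a8 (-1.70), S100a9 (-1.25), Smo (2.03) and Tcf21 (3.82) among the genes named in both contrasts. For Hhip the level in marked muscle cells lay under the lower quartile. Camera at the preset correlation called the difference for the lists endothelial (-3.34), lymphatic endothelial (1.34), hedgehog targets (1.55), hedgehog components (0.65), myogenic progenitor (3.14), myoblast differentiation (2.01), sarcomere (3.19), head mesoderm (0.97), fibro-adipogenic and fibroblast (3.52), tenocyte (1.71), pericyte and smooth muscle (2.03), neutrophil (-2.74), Schwann and glial (0.97), cell cycle (1.36), mesenchymal transition factors (0.99), rhabdomyosarcoma reference (2.18), imprinted growth network (1.43) and ribosomal proteins (0.27), each with its median. With an estimated correlation 15 of these 18 calls were lost (adjusted p = 0.0736 to 0.439). All these differences are tied to the Pecam1 gate.

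Of 20 genes of salivary glands, which lie near the sternocleidomastoid muscle, 6 were over 1 (log2) higher in the mean of muscle repeats 1 and 2 than in repeat 3 in both populations. Over 1 above repeat 3 of the same population were, in repeat 1, 6 genes in Tomato-positive and 15 in Tomato-negative cells and, in repeat 2, 7 and 5, and the list median lay 0.92 above the array median in repeat 1, 0.06 above in repeat 2, at -0.96 in repeat 3 and at -1.73 in the tumor arrays. Transcription by the Tomato-positive cells is argued against, since in 0 of 3 repeats the list stood over 1 higher in them (-2.40, 0.13 and 0.04), and so is the separate normalization of muscle and tumor, since the list still differed by 1.88 between muscle repeats after centring. Carried-over gland tissue missed its bound of 1 in 2 (6 of 20), but this averaged 2 unlike repeats and counted 8 dim genes. Of 10000 random lists 0 rose as far over repeat 3 (list median 1.2), so carry-over remains open.

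Same-numbered tumor arrays deviated from their population means in opposite directions. Equal means force this: the 4 repeat-number means differed by at most 7.67e-05 at every probe set. Taking these means out before deposit is a candidate cause of the equality. Exchanged population labels are argued against, since 0 of 12 tumor arrays correlated best with an array of another population. So is the younger age of repeat 4, since the means of repeats 1 to 3 were equal too (mean correlation -0.49, 9 pairs). No other biological explanation was tested.

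Xist, the transcript that silences 1 X chromosome, was high in all 6 muscle arrays (10.17 to 10.85) and low in all 12 tumor arrays (5.05 to 5.79). The separate normalization of both tissues is argued against: after centring the difference was -5.50, where the central 99 percent of genes lay between -1.73 and 2.04. Female muscle and male tumors stay open. Y-linked Kdm5d, Uty and Eif2s3y would then be higher in tumor but differed by 0.00, -0.60 and -0.59 (mean -0.40). No array of known sex tested their probes. Muscle pooled from both sexes with tumors from males cannot be told apart either, since no level of a pool was bounded beforehand and the highest tumor value was 5.79. Strain and age were not tested as causes.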

How the results depend on the processing

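Leaving out muscle repeats 1 and 2, and the block with 48-day tumors only, were chosen after the data had been seen. No named gene and no list past the threshold was past it in the other direction under the alternatives run. Of all genes 1 in Pecam1-positive against Pecam1-negative marked cells and 2 in Pecam1-negative marked cells against muscle were so with the mean of all probe sets, as were 1 in the latter after quantile normalization and 1 in Pecam1-positive cells against muscle on centred values. In marked Pecam1-positive tumor cells against muscle the imprinted growth network list, at 0.01, lost its call at -0.34 on centred and -0.30 on quantile-normalized values, and Isl1 and Klf1, both 0.02, passed at -0.33 and -0.34 on centred values. Hspa8 in Pecam1-negative cells, at 0.02, passed at -0.32. Leaving out muscle repeats 1 and 2, with 1 muscle array per population assumed to vary like the other groups, gave 3629 genes for muscle, 4945 for marked Pecam1-positive tumor cells against muscle and 3992 for the difference. With at least a 2-fold change the counts were 2436 for muscle, 996 (304 higher and 692 lower), 2291 and 2310 (880 and 1430) for the tumor comparisons in the order of the text, 3189 (1661 and 1528) for the difference, and 3688 and 1237 on deposited values for tumor Pecam1-negative and Pecam1-positive cells against muscle (3074 and 737 on centred values), a stricter threshold by construction. For Pecam1-positive cells 1120 of these were higher and 117 lower, and on centred values 418 and 319. Marked against unmarked Pecam1-negative tumor cells gave 2693 genes with the repeat number as a block and 2440 at an adjusted p of 0.01. Marked Pecam1-positive tumor cells against muscle gave 5593 genes after quantile normalization and 5482 on centred arrays. Apart from that construction, the cause was not tested. With 1 array left out the counts ran from 5525 to 5913 for muscle, 2871 to 3993, 6394 to 6713 and 6042 to 6367 within tumors, and 9781 to 10150 and 7306 to 8184 for tumor against muscle. All other counts stayed within 1.5 times the count reported, for tumor against muscle that on deposited values (10590 and 8444), on which those alternatives were run. Over 1.5 times the 5482 on centred values were, for Pecam1-positive cells on deposited ones, no filter (11353), a random block (8751), array weights (8640), 48-day tumors (8555), the mean of all probe sets (8462) and a trended and robust variance (8405). Of 125 list tests within a tissue or on the difference 72 lost the call with an estimated correlation and 2 gained one with the block, and of 50 of tumor against muscle 18 lost it with an estimated correlation. Of 296 named gene results within a tissue or on the difference 19 lost the call with the block, and of 131 of tumor against muscle, where it joins different animals, 3 lost and 2 gained it. Of such gene results within a tissue or on the difference 12 of 235 lost the call with 48-day tumors only, 7 of 245 in fits of only the groups compared, where 1 gained it, and of 296 results 4 with no filter, 4 with array weights and 3 after quantile normalization. Of 100 such list tests 2 lost and 5 gained the call with 48-day tumors. Leaving out arrays was not run on lists. Signal over background was not measured on these arrays, and dim genes were left out.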

Other observations

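The lists in this part were written and tested after the data had been seen, and the other splits of the samples were planned. A list of activated and venular endothelium was higher in marked Pecam1-positive tumor cells than in marked muscle cells. Of its 15 genes 13 rose and 0 fell (centred median 1.65, adjusted p = 5.68e-09, and 0.0555 with an estimated correlation), among them Sele (3.33), Lrg1 (2.41), the chemokine receptor Ackr1 (1.65) and Selp (1.15). A list on fatty acid handling of muscle capillaries was lower there. Of its 14 genes 0 rose and 11 fell (median -1.08, adjusted p = 9.58e-07, and 0.0161 with an estimated correlation), among them the glycerol channel gene Aqp7 (-2.66), the metalloproteinase inhibitor gene Timp4 (-2.86), the lipoprotein lipase gene Lpl (-1.28), the transcription factor gene Tcf15 (-1.38) and the fatty acid receptor Cd36 (-0.93). In normal muscle 12 of these 14 genes were higher and 1 was lower in Tomato-positive cells (median 2.72, adjusted p = 3.01e-09, and 0.00636 with an estimated correlation). Tip cell genes, of sprouting vessels, were not called in the tumor endothelium against muscle (3 up and 1 down of 13, adjusted p = 0.203).

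Among Pecam1-negative tumor cells, genes of mast cells were lower in the marked cells. In that list 7 of 8 fell and 1, Gata2 (1.02), rose (median -2.78, adjusted p = 4.87e-10, and 0.00636 with an estimated correlation), with the histamine-forming enzyme gene Hdc at -3.74 and Tpsb2 at -3.04. All 11 antigen presentation genes fell there as well (median -1.82, adjusted p = 2.81e-09, and 0.0773 with an estimated correlation). The salivary gland list, with 12 genes past the filter, stood at a median of -1.50 in marked Pecam1-negative tumor cells against muscle (0 up and 7 down, adjusted p = 0.0594) and at -1.15 in Pecam1-positive ones (0 up and 5 down, adjusted p = 0.0191, and 0.541 with an estimated correlation).

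Other splits of the same arrays into groups of the same sizes were fitted for each comparison with only the groups compared and on deposited values, so the real counts differ from those above. In muscle 10 splits are too few for a share under 0.05; the real split gave 5670 genes and the highest other 0. Among the 4 splits that part as many same-numbered pairs, the real one included, the highest other gave 0. Within tumors 1 of 35 splits, the real one, gave as many genes in each comparison, but the equal means of the repeat numbers tie same-numbered arrays, and the 8 splits that part as many pairs are too few for a share under 0.05. The counts were 3899 against a highest other of 1 for marked against unmarked Pecam1-negative tumor cells, 6979 against 6 for Pecam1-positive against Pecam1-negative marked cells and 6093 against 0 across both markers, and among the 8 splits the highest others were 1, 0 and 0. Against muscle 1 of 35 splits, the real one, gave as many: 10703 genes against 0 for Pecam1-negative cells and 7629 against 188 for Pecam1-positive ones. The 188 came from grouping the 3 muscle arrays with tumor repeat 4. On centred arrays the counts were 9485 against 2 and 4243 against 240. These argue against chance but cannot part tissue from separate processing. For the difference 1 of 100 regroupings, the real one, gave 6301 genes, and the highest other 4288, from a regrouping that kept the muscle populations and mixed the tumor ones; these regroupings did not keep to the pairs.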
